A study of Mus musculus with 6 samples.

How the data were processed

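RNA-seq was done on immortalized mouse brown preadipocytes differentiated to day 7 and treated for 16 h with 100 nM rotenone or with DMSO, in 3 deposited libraries per group. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with a NEBNext Ultra RNA kit for Illumina sequencing. Whether polyadenylated RNA was selected is not given in the sources used here. Each deposited file holds whole-number counts of reads per gene symbol, not normalized, for 26214 genes. Per the submitters' processing notes, TopHat2 and the mouse build mm10 were used; no version is given. The counting program, the gene annotation and whether strand was used are not given in the sources used here. Whether genes that overlap or lie antisense to one another were told apart in these counts is therefore unknown. Nothing in the sources used here shows whether multi-mapped reads were counted, and values of near-identical copies are therefore uncertain.

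Before testing, libraries of each group were compared. The 3 rotenone files had 0 genes with different counts and entered as 1 library. Every pair of DMSO libraries differed, with a Pearson correlation across genes of 0.998 in each pair, and the genes are not independent replicates. The labels call the replicates independent. Nothing further says whether they were separate cultures, so p-values of single genes measure the spread between these libraries, which may be technical. DMSO libraries held 29194179, 28209306 and 26085061 counts and the rotenone library 21611589, and 16577, 16484, 16355 and 15693 genes had at least 1 count. The ribosomal RNA precursor gene Rn45s took 3.17%, 2.58% and 2.51% of DMSO counts and 3.91% of rotenone counts.

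Counts were scaled by the TMM method and filtered by expression with the defaults of filterByExpr in edgeR 4.0.16 (R 4.3.3), which left 14709 genes. edgeR's robust quasi-likelihood F test compared rotenone with DMSO, with 2 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested. The threshold was an adjusted p of 0.05. The standard error of a log2 fold change was its size divided by the square root of F. Levels are given in CPM on TMM-scaled library sizes. Gene lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, and again with a correlation estimated for each list; p-values were adjusted over the 28 lists with a measured member, of 29 fixed before the data were examined. At the preset correlation camera weighs the members of a list against the other genes. Its p-values then treat genes as the units and do not measure the spread between libraries. A count of genes adjusted over the list alone uses the Benjamini-Hochberg method within that list.

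Genes were named by a rule set before the data were examined: 16 fixed genes; the 6 largest rises and 6 largest falls among genes past the threshold with a mean of at least 5 CPM, leaving out predicted genes and small RNAs; and up to 4 members of each list with the largest changes past the threshold. Pdgfra, Zfp521 and the genes named from lists added later were chosen after their values were seen. A few genes that the rule names are not reported here. Positions are from GENCODE M21 on GRCm38.

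The tests were tried on simulated counts with the means and library sizes of the real libraries. Among the genes changed by 1.5-fold, 2-fold and 4-fold, 60.0%, 81.2% and 93.8% were called in the right direction, and 2.5% of all calls were false. In that simulation 198 of 14362 genes were changed, a far smaller share than was called in the real data. These rates therefore need not hold there. With no gene changed, edgeR called 0 genes, and with the lone library varying by 20% it called 3218 of 14365. Camera called 2 of 2 changed lists and 0 unchanged lists. Genes were simulated independently of one another, so this does not show how camera at its preset correlation behaves on lists with correlated members. The correction for transcript length and GC content used the longest annotated transcript of each of 14413 genes in 8 by 8 bins; in a simulated length trend it took the median of an unchanged list from 0.57 to -0.02.

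Alternatives fixed in advance were other scalings (median-ratio, upper quartile, library size only), other filters, leaving out each DMSO library, treating every file as independent, a non-robust prior, an adjusted p of 0.01, a test against a 1.5-fold change, limma-voom, DESeq2 1.42.0, fry and lists without shared members. After the data were seen, 2 alternatives were added, leaving out Rn45s and assuming a coefficient of variation of 20%, together with 9 gene lists chosen because members had stood out.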

Results

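Gene expression was measured by RNA-seq in immortalized mouse brown adipocytes, which are fat cells of the heat-producing kind, grown from preadipocytes and differentiated in culture. On day 7 of differentiation the cells received 100 nM rotenone, an inhibitor of complex I (NADH dehydrogenase) of the mitochondrial respiratory chain, or its solvent DMSO for 16 h. Each group had 3 deposited libraries, and the labels describe them as independent replicates. The 3 rotenone files held identical counts for all 26214 listed genes, a difference smaller than sampling noise, so they were counted as 1 sample. The 3 DMSO libraries differed from one another, with a chi-square per gene of 8.91, 8.07 and 5.21 for the 3 pairs. The comparison was therefore between 3 DMSO libraries and 1 rotenone library, and the spread came from the DMSO libraries alone. Total counts were 29194179, 28209306 and 26085061 in DMSO replicates 1, 2 and 3 and 21611589 in the rotenone library. At these depths a count of 0 allowed a level of up to 0.103 to 0.139 CPM (counts scaled to library size), which covers counting error only.

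The comparison addressed how gene expression in differentiated brown adipocytes differs with rotenone. No other complex I inhibitor was used, so effects through complex I could not be told apart from other effects of rotenone. Transcripts of the integrated stress response and of ER chaperones were mostly higher with rotenone, and those of the hypoxia response and glycolysis mostly lower. These 4 lists passed limma's camera test at its preset correlation, but no list passed with an estimated correlation. The preset form takes genes as its units, so its p-values do not measure the spread between libraries. The estimated form rests on the 2 residual degrees of freedom of the fit. Failing it therefore does not by itself show that members of a list are correlated. Fgf21, a hormone released by stressed metabolic tissues, rose by 2.87 ± 0.21 (log2 fold change ± SE), from 2.38 ± 0.32 CPM (SD, n = 3) to 17.4 CPM in the rotenone library (n = 1). Ucp1, the uncoupling protein that produces heat in brown fat, fell by 1.86 ± 0.21 on the log2 scale, from 67.2 ± 11 CPM (SD, n = 3) to 18.5 CPM. Of 14709 genes tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 4054 were higher and 4197 lower with rotenone at an adjusted p under 0.05, and 814 and 1668 of them by at least 2-fold. With scaling by library size only, 3245 genes were higher and 5153 lower, and the median log2 fold change of all genes moved from -0.04 to -0.16.

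These calls assume that rotenone libraries vary as little as the DMSO libraries did, with a biological coefficient of variation of 6.9%. When unchanged genes were simulated with a lone library that varied by 20%, 3218 genes were called by the same edgeR test, and with a coefficient of variation of 20% assumed in the real data 1408 genes were higher and 2063 lower.

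Among genes with a mean of at least 5 CPM, the 6 largest rises were those of Hspa1b, Hspa1a, Nr1d1, Fgf21, Cnn1 and Atf3. Hspa1b and Hspa1a encode inducible HSP70 chaperones and rose by 3.37 ± 0.08 and 3.34 ± 0.10 on the log2 scale; they are near-identical copies, so the division of reads between them is uncertain. Nr1d1, which encodes the clock repressor REV-ERB alpha, rose by 2.91 ± 0.07, from 72.3 ± 5.3 CPM (SD, n = 3) to 542 CPM. Cnn1, a calponin of smooth muscle, rose by 2.85 ± 0.23, and Atf3, a stress-induced transcription factor, by 2.83 ± 0.11. Among the largest falls were those of Elf3, Ankrd37, Smim41, Rasd1 and Rassf4. Elf3, an epithelial-type ETS factor, stood at 7.62 ± 0.75 CPM (SD, n = 3) in DMSO and had 0 counts with rotenone, which made it at least 51.5-fold lower against a floor of 3 counts in that library (0.148 CPM after TMM scaling). Ankrd37, a target of hypoxia-inducible factor, had a log2 fold change of -6.26 ± 0.25. Smim41 gave -6.22 ± 0.23, Rasd1 -5.60 ± 0.33 and Rassf4 -5.50 ± 0.19.

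More peroxisomal genes, and more genes driven by the nuclear receptors of the PPAR family, fell than rose. Ppara, a receptor that switches on fatty acid oxidation genes, fell by 1.46 ± 0.08 on the log2 scale, from 173 ± 8.3 CPM (SD, n = 3) to 62.5 CPM, and Pparg, the main adipogenic receptor, fell by 0.65 ± 0.07. Pex11a, which acts in peroxisome division, fell by 0.57 ± 0.08, and Pex5, the import receptor for peroxisomal enzymes, fell by 0.32 ± 0.08. Abcd2, a transporter of very long-chain fatty acids, fell by 1.78 ± 0.32. Cat, which encodes catalase, gave 0.01 ± 0.06 and Ppargc1a, a coactivator of mitochondrial biogenesis, gave -0.08 ± 0.09, neither past the threshold, and the sign for Cat turned with the scaling. With a coefficient of variation of 20% assumed, Pparg, Pex11a and Pex5 no longer passed the threshold.

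Of 16 measured peroxin genes, which build the organelle, 2 rose and 9 fell (2 and 9 adjusted over the list alone, 1 and 2 with the 20% coefficient of variation), with a median log2 fold change of -0.32. Pex14 rose by 1.02 ± 0.07, while Pex6 fell by 0.99 ± 0.09. The list did not stand apart from other genes by limma's camera (Benjamini-Hochberg adjusted p = 0.14; adjusted p = 0.44 with an estimated correlation). Of 46 peroxisomal enzymes and transporters, 3 rose and 25 fell (3 and 25 adjusted over the list alone; 0 and 8 with the 20% coefficient of variation), with a median of -0.26. Camera in limma gave a Benjamini-Hochberg adjusted p of 0.022, against an adjusted p = 0.44 with an estimated correlation and 0.068 without members shared between lists. Log2 fold changes were -3.13 ± 0.45 for Mpv17l, -2.36 ± 0.17 for Ehhadh, the bifunctional enzyme of peroxisomal beta-oxidation, and -1.38 ± 0.10 for Hacl1. Of 43 PPAR target genes, 7 rose and 24 fell (8 and 24 adjusted over the list alone, 1 and 10 with the 20% coefficient of variation). Their median was -0.34, with a limma camera Benjamini-Hochberg adjusted p = 0.03 (adjusted p = 0.5 with an estimated correlation, and 0.093 on the 14 genes in no other list). Angptl4, a secreted inhibitor of lipoprotein lipase (chromosome 17, 33773750 to 33781830, GRCm38), fell by 2.63 ± 0.08. Ucp3 fell by 3.58 ± 0.51, from 4.16 CPM in DMSO to 7 counts in the rotenone library. Fgf21, which is also in this list, rose by 2.87 ± 0.21.

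Brown fat and general fat cell genes were lower in part. Of 22 thermogenic genes, 6 rose and 11 fell (6 and 11 adjusted over the list alone, 0 and 8 with the 20% coefficient of variation, 3 and 11 with library size scaling). Their median was -0.15 (-0.27 with library size scaling), with a limma camera Benjamini-Hochberg adjusted p = 0.2 (adjusted p = 0.5 with an estimated correlation). Prdm16, a determinant of brown fat identity, fell by 2.13 ± 0.14, beside Ucp1 (chromosome 8, 83290352 to 83298452, GRCm38). Kcnk3 and Otop1 gave -1.98 ± 0.09 and -1.79 ± 0.29. Of 30 general adipocyte genes, 4 rose and 16 fell (4 and 16 adjusted over the list alone, 0 and 7 with the 20% coefficient of variation). Their median was -0.32, with a limma camera Benjamini-Hochberg adjusted p = 0.013 (adjusted p = 0.5 with an estimated correlation, and 0.081 on the 13 genes in no other list). Cebpa, an adipogenic transcription factor, fell by 2.31 ± 0.08, from 558 ± 24 CPM (SD, n = 3) to 112 CPM. Log2 fold changes were -2.38 ± 0.10 for Acvr1c, -1.94 ± 0.12 for the leptin gene Lep and -1.88 ± 0.07 for Lipe, hormone-sensitive lipase. Fabp4, an abundant fatty acid carrier of fat cells, gave 0.05 ± 0.07 and did not pass the threshold, a value that was 0.12 and did pass without DMSO replicate 1 and -0.07 with library size scaling.

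**Figure D1:**
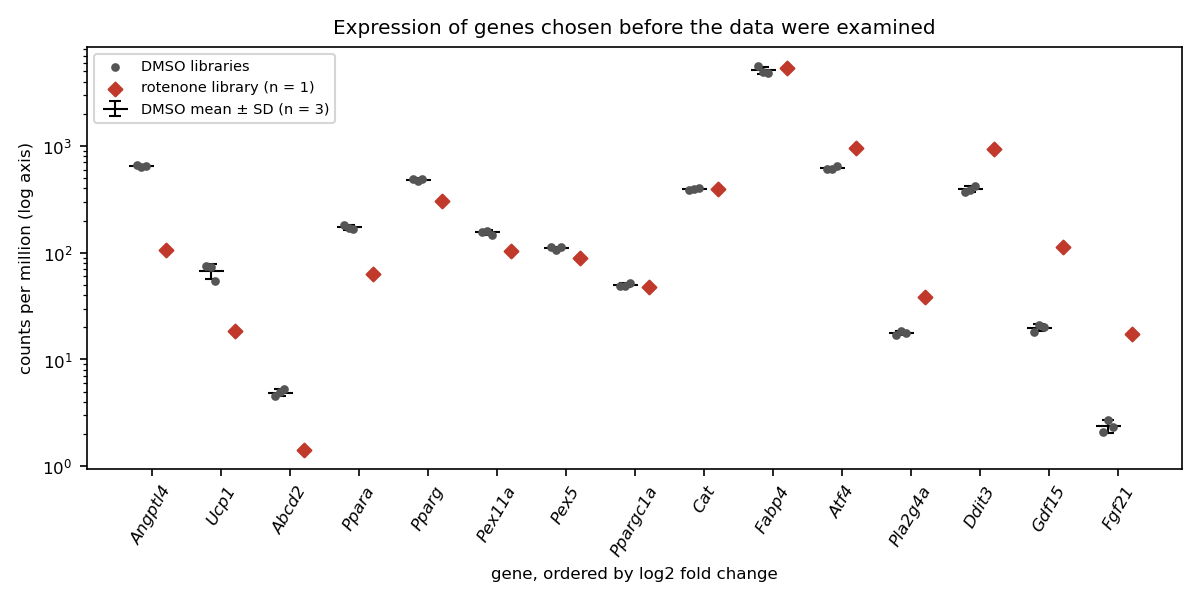
Expression of genes chosen before the data were examined, in CPM (counts scaled to library size) on a log axis. Grey points are the 3 DMSO libraries with their mean and SD, and red diamonds are the single rotenone library: Angptl4 lies lowest relative to DMSO (105 against 647 CPM) and Fgf21 highest (17.4 against 2.38 CPM), while Cat and Fabp4 lie close to DMSO, with signs that depend on the scaling.

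Markers of other cell types were measured beside the fat cell genes. Of 20 preadipocyte and fibroblast markers, 12 rose and 2 fell (12 and 2 adjusted over the list alone, 9 and 2 with the 20% coefficient of variation). Their median was 0.79, with a limma camera Benjamini-Hochberg adjusted p = 0.0025 (adjusted p = 0.31 with an estimated correlation). Acta2, the smooth muscle actin, rose by 2.46 ± 0.06, from 155 ± 8.9 CPM (SD, n = 3) to 852 CPM, Tagln by 2.43 ± 0.08 and Mgp by 2.02 ± 0.13. The 2 that fell, named after their values were seen because the count was small, were Pdgfra (-1.11 ± 0.16) and Zfp521 (-1.11 ± 0.35). Skeletal muscle markers were measured for 6 genes, of which 1 rose and 2 fell (1 and 3 adjusted over the list alone, 1 and 2 with the 20% coefficient of variation), with a median of -0.69 and a mean of -0.02 (limma camera Benjamini-Hochberg adjusted p = 0.44; adjusted p = 0.57 with an estimated correlation). Acta1 rose by 4.87 ± 0.45 from 0.222 CPM, while Tnnc1 and Des gave -1.38 ± 0.49 and -0.29 ± 0.09. The calls for Tnnc1 and Des were lost with DESeq2, and that for Tnnc1 also without DMSO replicate 3. Of 3 macrophage markers, Cd68 rose by 2.38 ± 0.23 and none fell (1 and 1 adjusted over the list alone, 1 and 1 with the 20% coefficient of variation), with a median of -0.06 and a mean of 0.38 with a gene at 0 counts set to its floor; limma's camera pointed up with a Benjamini-Hochberg adjusted p of 0.88 (adjusted p = 0.89 with an estimated correlation). Of 4 endothelial markers, Eng rose by 1.25 ± 0.33 and Egfl7 by 0.62 ± 0.23 (2 and 0 adjusted over the list alone, 1 and 0 with the 20% coefficient of variation; median 0.61, limma camera Benjamini-Hochberg adjusted p = 0.14; adjusted p = 0.44 with an estimated correlation), and Egfl7 did not pass with DESeq2.

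Genes of collagens and other matrix proteins were higher together. Of 33 measured, 29 rose and 1 fell (29 and 1 adjusted over the list alone, 23 and 0 with the 20% coefficient of variation). Their median was 1.05, with a limma camera Benjamini-Hochberg adjusted p = 2.3e-09 (adjusted p = 0.31 with an estimated correlation). Timp1, an inhibitor of matrix proteases, rose by 2.41 ± 0.15, the fibronectin gene Fn1 by 1.62 ± 0.06, from 627 ± 7.1 CPM (SD, n = 3) to 1920 CPM, Bgn by 1.61 ± 0.06 and Mmp2 by 1.58 ± 0.09.

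Hypoxia response and glycolysis genes had the lowest medians of the lists with at least 10 measured members. Of 22 hypoxia response genes, 1 rose and 21 fell (1 and 21 adjusted over the list alone; 1 and 16 with the 20% coefficient of variation). Their median was -1.88, with a limma camera Benjamini-Hochberg adjusted p = 2.6e-08 (adjusted p = 0.39 with an estimated correlation). Egln3, an oxygen-sensing prolyl hydroxylase, fell by 4.91 ± 0.09, from 1030 ± 25 CPM (SD, n = 3) to 34.1 CPM. Ndufa4l2 gave -4.24 ± 0.11 and the mitophagy receptor gene Bnip3 -3.10 ± 0.08. Of 22 glycolysis genes, 2 rose and 17 fell (2 and 17 adjusted over the list alone; 2 and 15 with the 20% coefficient of variation). Their median was -1.36, with a limma camera Benjamini-Hochberg adjusted p = 8e-06 (adjusted p = 0.31 with an estimated correlation). Ldha, lactate dehydrogenase A, fell by 2.17 ± 0.07, from 3810 ± 22 CPM (SD, n = 3) to 844 CPM. Aldoc gave -3.87 ± 0.14, the lactate exporter gene Slc16a3 -3.75 ± 0.13 and Pfkl -1.94 ± 0.07.

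Subunits of the respiratory chain were modestly higher. Of 36 complex I subunits encoded in the nucleus, 30 rose and 1 fell (31 and 1 adjusted over the list alone; 2 and 0 with the 20% coefficient of variation), with a median of 0.44. Ndufa11 rose by 0.94 ± 0.07, from 91.5 ± 3.3 CPM (SD, n = 3) to 175 CPM, and Ndufb7 by 0.87 ± 0.08. Limma's camera gave a Benjamini-Hochberg adjusted p of 2.3e-06 (adjusted p = 0.44 with an estimated correlation). Of 43 subunits of complexes II to V, 38 rose and 3 fell (39 and 4 adjusted over the list alone; 2 and 0 with the 20% coefficient of variation). Their median was 0.31 (0.19 with library size scaling), with a limma camera Benjamini-Hochberg adjusted p = 2.9e-06 (adjusted p = 0.44 with an estimated correlation). Cox6a2 rose by 1.23 ± 0.16 and Atp5g1 by 1.09 ± 0.08. Short transcripts were also higher in general in the rotenone library. Its median log2 ratio was 0.22 in the shortest length decile of genes and -0.26 in the longest, whereas single DMSO libraries lay between -0.03 and 0.04. After the length and GC correction the list medians were 0.27 for complex I and 0.21 for complexes II to V. Of 24 genes of the TCA cycle and pyruvate entry, 14 rose and 1 fell (16 and 2 adjusted over the list alone, 1 and 0 with the 20% coefficient of variation). Their median was 0.23 (0.11 with library size scaling), with a limma camera Benjamini-Hochberg adjusted p = 0.0023 (adjusted p = 0.56 with an estimated correlation); Mpc2, a pyruvate carrier, rose by 0.88 ± 0.06. Of 21 mitochondrial fatty acid oxidation genes, 6 rose and 7 fell (7 and 7 adjusted over the list alone, 0 and 2 with the 20% coefficient of variation, 2 and 9 with library size scaling), with a median of 0.02, a mean of -0.15 and a downward camera test in limma (Benjamini-Hochberg adjusted p = 0.91; adjusted p = 0.98 with an estimated correlation). The median of this list turned to -0.1 with library size scaling and to -0.02 with upper quartile scaling. Cpt2, which returns fatty acids to coenzyme A inside mitochondria, fell by 1.48 ± 0.09 and Hadhb fell by 1.24 ± 0.09. None of the 13 genes encoded in mitochondrial DNA was listed, so they were not analysed here.

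**Figure D2:**
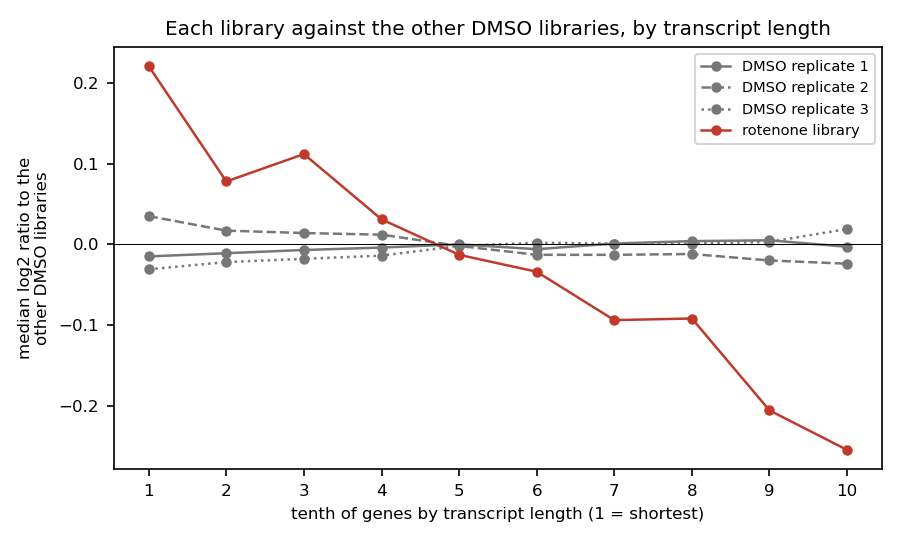
Median log2 ratio of each library to the other DMSO libraries, in 10 groups of genes of rising transcript length. The rotenone library (red) runs from 0.22 in the shortest decile to -0.26 in the longest, and the 3 DMSO libraries (grey) stay between -0.03 and 0.04.

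Genes of the integrated stress response and ER chaperones were mostly higher. Of 43 integrated stress response genes, 32 rose and 6 fell (32 and 7 adjusted over the list alone; 23 and 3 with the 20% coefficient of variation). Their median was 0.87, with a limma camera Benjamini-Hochberg adjusted p = 1.1e-06 (adjusted p = 0.42 with an estimated correlation). Gdf15, a stress-induced hormone, rose by 2.51 ± 0.09, from 19.8 ± 1.5 CPM (SD, n = 3) to 112 CPM, Ddit3 (CHOP) by 1.26 ± 0.07 and Atf4, the central transcription factor of the response, by 0.63 ± 0.06, a call lost with the 20% coefficient of variation. Ddit4, which is also induced by hypoxia, fell by 4.21 ± 0.09. Of 18 mitochondrial chaperones and proteases, 11 rose and 3 fell (11 and 4 adjusted over the list alone, 3 and 0 with the 20% coefficient of variation). Their median was 0.34 (0.22 with library size scaling), with a limma camera Benjamini-Hochberg adjusted p = 0.03 (adjusted p = 0.39 with an estimated correlation), a call lost without DMSO replicate 3 (adjusted p = 0.052 by limma's camera). Hspe1 and Hspd1, the partners of the mitochondrial chaperonin, rose by 1.46 ± 0.06 and 1.11 ± 0.06, while the protease subunit gene Clpx fell by 0.89 ± 0.08. Of 21 ER chaperone and unfolded protein response genes, 17 rose and 1 fell (17 and 1 adjusted over the list alone, 8 and 0 with the 20% coefficient of variation). Their median was 0.49, with a limma camera Benjamini-Hochberg adjusted p = 0.00013 (adjusted p = 0.31 with an estimated correlation). Hspa5 (BiP) rose by 1.70 ± 0.06, from 529 ± 25 CPM (SD, n = 3) to 1720 CPM, and Hyou1 by 1.39 ± 0.08. Of 27 oxidative stress genes under NRF2, 13 rose and 5 fell (13 and 5 adjusted over the list alone, 2 and 0 with the 20% coefficient of variation, 9 and 6 with library size scaling). Their median was 0.25 (0.13 with library size scaling), with a limma camera Benjamini-Hochberg adjusted p = 0.12 (adjusted p = 0.56 with an estimated correlation). The ferritin genes Ftl1 and Fth1 rose by 1.13 ± 0.07 and 0.93 ± 0.06, and Srxn1 fell by 0.87 ± 0.07.

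Lipid synthesis and arachidonic acid genes went both ways. Pla2g4a, the cytosolic phospholipase that releases arachidonic acid (chromosome 1, 149829618 to 149961290, GRCm38), rose by 1.12 ± 0.12, from 17.7 ± 0.7 CPM (SD, n = 3) to 38.4 CPM. Among 37 genes of arachidonic acid release and metabolism, 10 rose and 7 fell (10 and 7 adjusted over the list alone, 5 and 3 with the 20% coefficient of variation, 9 and 9 with library size scaling), with a median of 0.13, a mean of -0.12 and an upward camera test in limma (Benjamini-Hochberg adjusted p = 0.25; adjusted p = 0.49 with an estimated correlation). With library size scaling the median of this list was 0.01. The cyclooxygenase gene Ptgs1 rose by 1.44 ± 0.17 and Ptgis by 1.21 ± 0.18, and Pla2g4b fell by 1.27 ± 0.21. Ptgfr, a prostaglandin receptor, stood at 1.35 CPM in DMSO and had 0 counts with rotenone, at least 9.15-fold lower against the floor of 3 counts, and with genes at 0 counts set to that floor the mean of the list was 0.01. Of 25 fatty acid and triglyceride synthesis genes, 4 rose and 11 fell (4 and 11 adjusted over the list alone, 1 and 3 with the 20% coefficient of variation, 3 and 15 with library size scaling). Their median was -0.13 (-0.25 with library size scaling), with a limma camera Benjamini-Hochberg adjusted p = 0.14 (adjusted p = 0.5 with an estimated correlation). Gpam and Pnpla3 gave -1.90 ± 0.09 and -1.87 ± 0.10, and Mid1ip1 rose by 1.42 ± 0.08. Of 26 cholesterol synthesis and uptake genes, 10 rose and 5 fell (11 and 5 adjusted over the list alone, 1 and 0 with the 20% coefficient of variation), but 7 rose and 9 fell with library size scaling. Their median was 0.18 (0.06 with library size scaling), with a limma camera Benjamini-Hochberg adjusted p = 0.27 (adjusted p = 0.58 with an estimated correlation); Sqle, an enzyme of sterol synthesis, rose by 1.02 ± 0.06.

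Inflammatory, lysosomal and cell cycle genes were mostly higher. Of 21 inflammatory genes, 14 rose and 1 fell (15 and 1 adjusted over the list alone, 13 and 0 with the 20% coefficient of variation). Their median was 1.05, with a limma camera Benjamini-Hochberg adjusted p = 3e-04 (adjusted p = 0.31 with an estimated correlation). The chemokine genes Cxcl1, Cxcl10 and Ccl7 rose by 3.57 ± 0.27, 2.70 ± 0.22 and 2.23 ± 0.23, from 1.12, 3.02 and 2.65 CPM. Of 30 interferon-stimulated genes, 4 rose and 1 fell (4 and 1 adjusted over the list alone, 9 and 1 with the 20% coefficient of variation), but 3 rose and 4 fell with library size scaling and 4 and 3 with upper quartile scaling. Their median was 0.46, with a limma camera Benjamini-Hochberg adjusted p = 0.068 (adjusted p = 0.71 with an estimated correlation), and this test passed without DMSO replicate 2, where limma's camera gave an adjusted p of 0.0012. Zbp1, a nucleic acid sensor, rose by 2.22 ± 0.35 from 1.4 ± 0.55 CPM (SD, n = 3) and Mx2 by 1.13 ± 0.33 from 3.32 ± 1.3 CPM. Cmpk2 fell by 1.38 ± 0.43 from 3.2 ± 1 CPM. For this list the 20% coefficient of variation was not the stricter setting, since it gave more rises than the main test. Of 29 lysosome and autophagy genes, 23 rose and 1 fell (23 and 1 adjusted over the list alone, 12 and 1 with the 20% coefficient of variation). Their median was 0.67, with a limma camera Benjamini-Hochberg adjusted p = 2.9e-06 (adjusted p = 0.31 with an estimated correlation). The cholesterol exporter gene Npc1 rose by 1.74 ± 0.10 and Gabarapl1 by 1.36 ± 0.07, while Lipa, lysosomal acid lipase, fell by 1.29 ± 0.09. Of 20 p53 target genes, 9 rose and 7 fell (9 and 7 adjusted over the list alone, 5 and 2 with the 20% coefficient of variation, 9 and 8 with library size scaling). Their median was 0.19 (0.07 with library size scaling), with a limma camera Benjamini-Hochberg adjusted p = 0.34 (adjusted p = 0.5 with an estimated correlation); Gadd45a rose by 2.76 ± 0.06, from 107 ± 3.9 CPM (SD, n = 3) to 721 CPM. Of 30 cell cycle genes, 23 rose and 2 fell (23 and 2 adjusted over the list alone; 5 and 0 with the 20% coefficient of variation). Their median was 0.58, with a limma camera Benjamini-Hochberg adjusted p = 7.3e-06 (adjusted p = 0.31 with an estimated correlation). Cdc20 rose by 1.27 ± 0.07, from 63.6 ± 0.49 CPM (SD, n = 3) to 153 CPM, and Mcm2 by 1.24 ± 0.07.

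**Figure D3:**
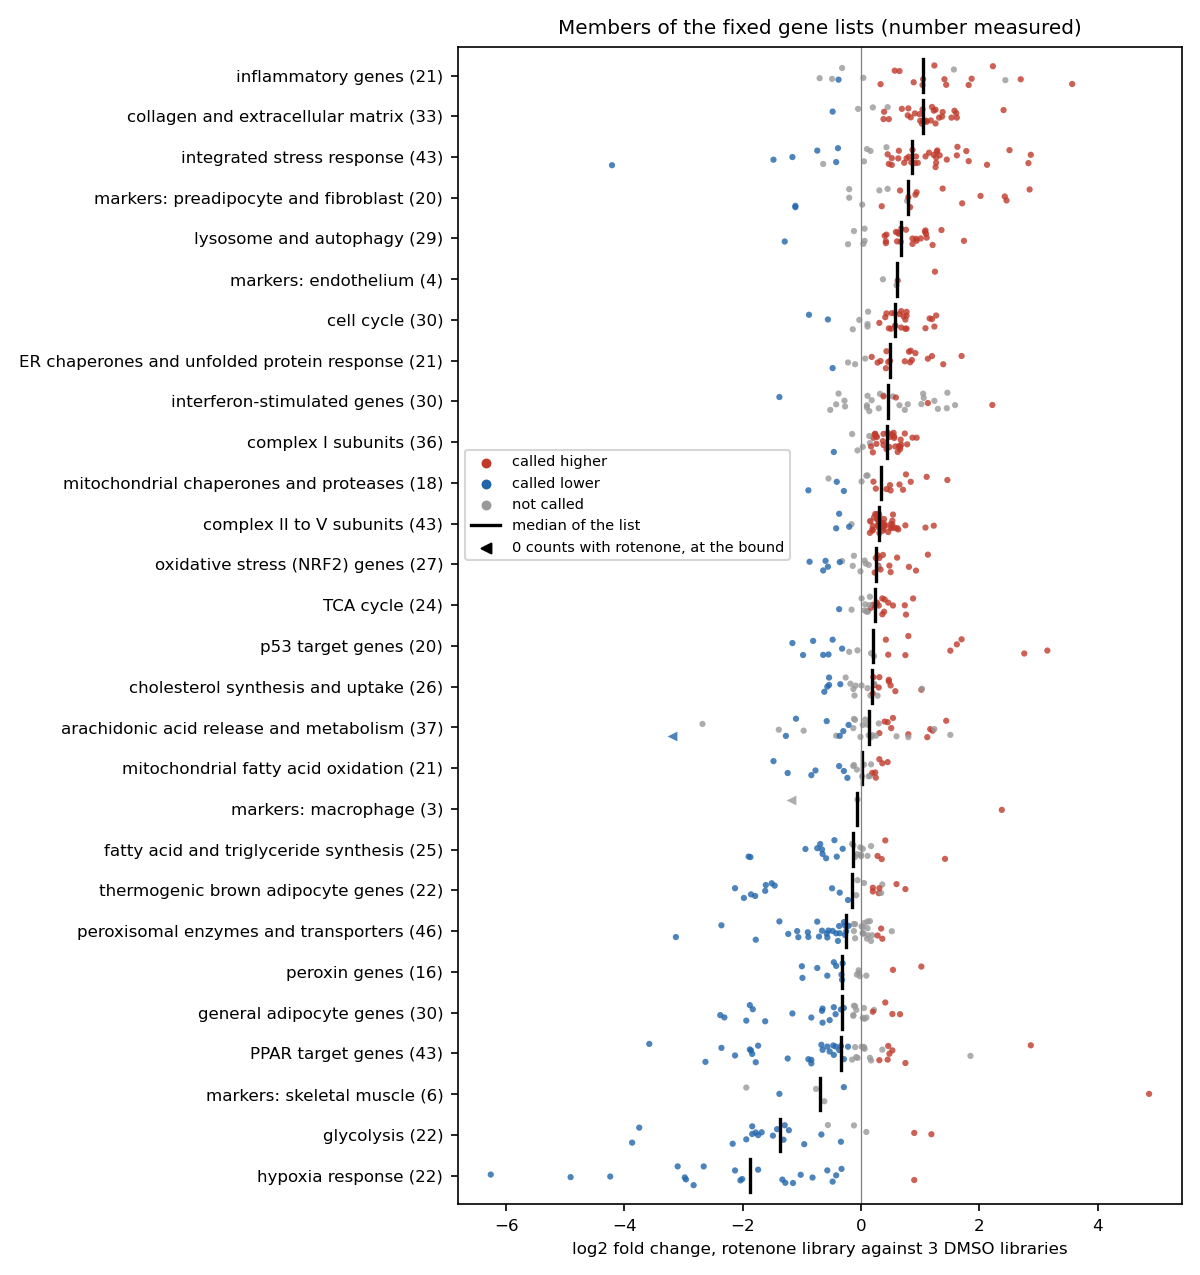
Log2 fold change of every measured member of the gene lists fixed before the data were examined, rotenone library against 3 DMSO libraries. Each point is a gene, coloured by its call, triangles are genes with 0 counts in the rotenone library drawn at the bound set by 3 counts, and black lines are list medians, which run from -1.88 for the hypoxia response to 1.05 for the inflammatory and the collagen and extracellular matrix lists.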

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

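Leaving out Rn45s and assuming a coefficient of variation of 20% were chosen after the data were seen; the other alternatives were fixed before. No paired analysis was possible because the 3 rotenone files hold 1 library, so replicate numbers do not mark separate rotenone samples; leaving out a rotenone replicate changes nothing for the same reason, and pseudocounts and the removal of mitochondrially encoded genes did not apply. Main calls were 4054 higher and 4197 lower. Other scalings and filters gave 3245 to 4194 higher and 3621 to 5153 lower, and leaving out each DMSO library 3977 to 4173 higher and 4076 to 4193 lower. Treating every file as independent gave 5391 and 5726, which counts 1 library 3 times. DESeq2 called 7037 genes, 7016 of them shared with edgeR in the same direction, and limma-voom 7700, 7586 of them shared. Testing against a 1.5-fold change gave 1203 higher and 1731 lower, and a coefficient of variation of 20% gave 1408 and 2063, of which 3049 were shared with the main test. The test against 1.5-fold demands a larger change by construction, while the fixed 20% also called genes that the main test did not.

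The estimated correlation lay below the preset 0.01 for matrix (-0.017), inflammatory (-0.015) and glycolysis genes (-0.004). It lay above the preset value for others, among them complex I (0.273) and the TCA cycle (0.669). Camera in this form rests on the 2 residual degrees of freedom of the fit, so failing it does not by itself point to correlated members. With an estimated correlation 0 lists passed. Adjusted p-values were then 0.31 for ER chaperones, glycolysis, inflammatory genes, lysosome, cell cycle, matrix and preadipocyte markers, 0.39 for mitochondrial chaperones and hypoxia response, 0.42 for the integrated stress response, 0.44 for peroxisomal enzymes, complex I and complexes II to V, 0.5 for PPAR targets and general adipocyte genes, and 0.56 for the TCA cycle. With fry, which tests members on their own, peroxins (0.015), thermogenic, fatty acid synthesis and p53 target genes (0.012 each) and endothelial markers (0.018) also passed. Without members shared between lists, peroxisomal enzymes (0.068), PPAR targets (0.093) and general adipocyte genes (0.081) no longer passed, with fewer genes per list, while thermogenic (0.031) and fatty acid synthesis genes (0.041) did. The interferon list passed with library size scaling (0.037) and without DMSO replicate 2 (0.0012; 0.0012 to 0.1 over the DMSO libraries left out). Mitochondrial chaperones did not at a mean of at least 5 CPM (0.069) or without DMSO replicate 3 (0.052; range 0.033 to 0.052). Lists that never passed turned direction for macrophage markers without a filter (0.71) and mitochondrial fatty acid oxidation without DMSO replicate 1 (0.86; range 0.74 to 0.89). Library size scaling shifted list medians down, which moved small ones by over 1.5 times: to 0.11 for the TCA cycle, 0.19 for complexes II to V, 0.22 for mitochondrial chaperones, 0.13 for NRF2 genes, 0.07 for p53 targets, 0.06 for cholesterol and 0.01 for arachidonic acid genes, -0.25 for fatty acid synthesis, -0.27 for thermogenic genes and -0.18 for macrophage markers, and of the lists added later to 0.11 for circadian clock genes and -0.04 for immediate early genes. The balance of calls turned from 4 higher and 1 lower to 3 and 4 for interferon-stimulated genes and from 10 and 5 to 7 and 9 for cholesterol genes. Mitochondrial fatty acid oxidation turned to -0.10, and to -0.02 with upper quartile scaling. All p-values here are from limma, adjusted by Benjamini-Hochberg. The log2 fold change of Cat turned to -0.11 with library size, -0.03 with upper quartile, -0.01 at a mean of at least 5 CPM and 0 with every file as independent, and that of Fabp4 to -0.07 with library size; neither was called in the main test. The cause was not tested unless stated.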

Other observations

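The tests of scaling, of cell shares and of other splits were chosen after the results were seen, as were all gene lists of the next paragraph; the test with all measured preadipocyte and fibroblast markers was added after the form limited to 20 CPM had given its result. The bounds of the length and GC content tests were set before their results were seen, but after the list medians were known. The 9 lists added were chosen because members stood out, so their p-values are not independent evidence.

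Cytosolic ribosomal protein genes were higher. Of 82 genes with cytosolic ribosomal protein symbols, 82 rose and 0 fell, with a median log2 fold change of 0.82 and a limma camera Benjamini-Hochberg adjusted p = 1.8e-20 over the 9 added lists (adjusted p = 0.32 with an estimated correlation); library size scaling left 81 higher and 0 lower. Of 78 mitochondrial ribosomal protein genes, 57 rose and 4 fell. Their median was 0.45 (limma camera Benjamini-Hochberg adjusted p = 3.4e-09; adjusted p = 0.28 with an estimated correlation). Of 57 replication-dependent histone genes, 36 rose and 1 fell. Their median was 1.67 (limma camera Benjamini-Hochberg adjusted p = 3.4e-09; adjusted p = 0.25 with an estimated correlation). Most of these histone genes stood under 1 CPM in DMSO, and those with the highest DMSO levels went both ways. H2bc4 (52.5 CPM in DMSO) and H1f2 (22.8 CPM) gave log2 fold changes of 1.9 and 2.18. H2ac19 (21.7 CPM) and H2ac18 (21.6 CPM) gave 0.4 and 0.41, and H2bc21 (26.2 CPM) gave -0.78. How RNA was selected is not known, and its effect on these genes was not tested. Many histone genes are near-identical, so single copies are uncertain. Only 49.1% had a length, which leaves the length check void for them. Of 18 actin cytoskeleton and contractile genes, 15 rose and 0 fell. Their median was 1.13 (limma camera Benjamini-Hochberg adjusted p = 3.9e-06; adjusted p = 0.29 with an estimated correlation); Tpm2 rose by 1.62 ± 0.07 and Srf by 1.16 ± 0.10. Of 18 cytosolic heat shock proteins, 12 rose and 1 fell. Their median was 0.5 (limma camera Benjamini-Hochberg adjusted p = 0.001; adjusted p = 0.32 with an estimated correlation), and Hspb1 rose by 2.22 ± 0.10.

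Among 19 circadian clock genes, 9 rose and 6 fell (7 and 6 with library size scaling). Their median was 0.23, or 0.11 with library size scaling (limma camera Benjamini-Hochberg adjusted p = 0.24; adjusted p = 0.4 with an estimated correlation); beside Nr1d1, Ciart rose by 1.86 ± 0.13 and Npas2 fell by 1.83 ± 0.43. Of 15 immediate early genes, 6 rose and 5 fell, with a median of 0.08 that turned to -0.04 with library size scaling (limma camera Benjamini-Hochberg adjusted p = 0.46; adjusted p = 0.72 with an estimated correlation). Myc rose by 2.17 ± 0.12, while the AP-1 gene Fosl1 fell by 4.91 ± 0.23, from 34.3 to 1.13 CPM. Of 15 MHC class I and antigen processing genes, 8 rose and 0 fell. Their median was 0.45 (limma camera Benjamini-Hochberg adjusted p = 0.014; adjusted p = 0.59 with an estimated correlation). Several genes often used as references in quantitative PCR moved: of 15 such genes 9 rose and 2 fell. Their median was 0.49 (limma camera Benjamini-Hochberg adjusted p = 0.024; adjusted p = 0.29 with an estimated correlation). Gapdh fell by 1.42 ± 0.07, from 12900 ± 520 CPM (SD, n = 3) to 4830 CPM, and Pgk1 fell by 1.78 ± 0.07, whereas Actb rose by 1.02 ± 0.07; Tbp gave 0.05 ± 0.13 and Ywhaz -0.02 ± 0.07, neither past the threshold.

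Respiratory chain and ribosomal protein transcripts are short, and short transcripts were higher in the rotenone library. The median of genes of like length and GC content was therefore subtracted. List medians were then 0.27 for complex I (95% bootstrap interval 0.12 to 0.41, 0.44 before) and 0.21 for complexes II to V (0.13 to 0.28, 0.31 before). Cytosolic ribosomal proteins gave 0.66 (0.62 to 0.72, 0.82 before) and mitochondrial ribosomal proteins 0.35 (0.27 to 0.44, 0.45 before). Without this correction, library size scaling put the mitochondrial ribosomal median at 0.33. A length or GC trend may therefore account for part of these rises, and under this correction it did not account for the whole. The genes of like length left out only the list under test, so they still held the other short lists that rose. Part of what was subtracted may be the rise of those lists, so the drops do not measure a length source. Lengths were those of the longest annotated transcript, so a gene that expresses a shorter one may be corrected too little. The intervals resample genes and not libraries, so a trend as the whole source is not excluded. Whether the remainder comes from rotenone or from some other property of this library stays open, since there was 1 rotenone library.

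The lower hypoxia response and glycolysis transcripts had medians of -1.81 and -1.38 after the length and GC correction. Decile medians of the log2 fold change ran only from 0.26 to -0.26 by length and from -0.18 to 0.05 by GC content. Trends that small could hardly have moved these list medians, so the outcome of the correction was all but fixed in advance. The values show only that both trends were small next to these falls. The hypoxia median ran from -2 to -1.86 over 4 scalings. A scaling shifts all genes alike and these scalings lay close together, so this range was all but fixed in advance and adds no support. A candidate explanation is weaker hypoxia signalling where inhibited respiration leaves more oxygen in the medium. It was named after the fall of 21 of 22 hypoxia genes had been seen, oxygen was not measured, and no value here tests it or tells it apart from any other loss of hypoxia signalling, so it stays open.

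Of 33 matrix genes 29 rose and of 20 preadipocyte and fibroblast markers 12 rose, while of 30 general adipocyte genes 16 fell, 4 rose and 10 were not called; the general adipocyte list did not pass limma's camera with an estimated correlation (Benjamini-Hochberg adjusted p = 0.5) or without shared members (adjusted p = 0.081). The matrix median was 1.27 after the length and GC correction (1.08 to 1.37), while that of general adipocyte genes was -0.35 with an interval that reached 0 (-0.65 to 0.01); the correction did not move that median toward 0 from -0.32, so a length or GC source meets the bound set for it without shrinking the change. A smaller share of adipocytes and nothing else would lower abundant adipocyte genes alike. The 25 genes at 100 CPM or more spread from -2.38 to 0.53 (interquartile range 0.76), which such a share alone would not give. A smaller share beside changes in single genes could give the same spread, so a smaller share is not excluded. A larger share of undifferentiated cells gave an answer that depended on the expression limit: 0 of 11 markers at 20 CPM or more fell and 10 rose, while 2 of all 20 measured markers fell, among them Pdgfra at 19.5 CPM, just under that limit. The largest rises among these markers, of Cnn1 (2.85), Acta2 (2.46) and Tagln (2.43), were of genes that are also in the actin cytoskeleton and contractile list. Those rises therefore do not speak for cell shares alone. A change of cell makeup may contribute, and neither form of the test for undifferentiated cells settles it.

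Each library in turn was set alone against the other 3 with edgeR. The rotenone library gave 8251 calls and the highest of the other splits 0, with 33, 13 and 22 genes at an unadjusted p under 0.05 for DMSO replicates 1, 2 and 3. When a DMSO library stood alone, the other group held the rotenone library, whose difference entered the residual spread, so low counts were built into those splits. As many calls came from 1 of 4 splits, and 4 splits are too few for a share under 0.05. As a description without a test, each library was also compared with the mean of the DMSO libraries other than itself, with 0.5 CPM added to each value, which were 3 for the rotenone library and 2 for a DMSO library. Among 10877 genes with a mean of at least 5 CPM, 486 were at least 2-fold higher and 894 at least 2-fold lower in the rotenone library. In single DMSO libraries at most 4 were higher and 3 lower.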
